A study of Mus musculus with 6 samples.

How the data were processed

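RNA was sequenced from 6 libraries of mouse CD4+ T cells, 3 from wild-type cells (WT) and 3 from cells labelled as Wtap knockout (Wtap KO). Group and replicate number were taken from the sample titles. Per the labels' protocols, cells received 4-hydroxytamoxifen at 1 µM for 24 h before activation with anti-CD3 at 1 µg/mL and anti-CD28 at 2.5 µg/mL. Th1 conditions, with IL-12 at 10 ng/mL and anti-IL-4 at 10 µg/mL, lasted 40 to 48 h. Cells were then moved to IL-2 at 200 IU/mL and harvested on day 4. Libraries were made with a Lexogen SENSE mRNA kit and read as pairs of 50 bp, per the labels. The protocol text is the same for every library, WT included, and gives the tamoxifen step as one for depletion of Wtap. Whether WT cells carried Cre, which part of Wtap was deleted and whether each library came from its own animal are not given in the sources used here.

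The authors deposited 1 table per library with 142647 transcripts, each with an estimated count, a TPM value, a length and an effective length. Per the submitters' processing notes, kallisto 0.44.0 and DESeq2 were used with the mouse build GRCm38 (mm10). kallisto assigns reads to transcripts by pseudoalignment and splits reads that fit several transcripts between them, so the deposited estimated counts need not be whole numbers, and the split between transcripts of 1 gene carries an error that the tables do not give. The deposited TPM values are estimated counts divided by effective length and scaled to a fixed total per library by the authors. The annotation release behind the index, the strand setting and the role of DESeq2 are not given in the sources used here. The length columns were used only to rebuild length-scaled counts.

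Transcripts were matched by identifier without version to GENCODE M21 (GRCm38). Of the transcripts, 99.15% matched, holding 99.71% to 99.75% of the estimated counts of a library, and 99.72% of the matched transcripts had the same length in the file and in the annotation. The 1218 unmatched transcripts were left out of the main test and kept as features of their own in an alternative. Estimated counts were summed per gene and rounded to whole numbers. Depth ranged from 32363139 to 44039467 estimated counts per library. For a share listed at 0 in each library of a group, the limit given is 3 counts over the gene's counts in the group, which covers counting error only.

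The planned choices, namely the groups, the tests, the gene lists, the rule for named genes and most alternatives, were set before the data were examined. Orai1 and Ripk1 were picked from knowledge of the study, so their results are no independent finds. Genes were tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3, robust, TMM normalization, filterByExpr) with genotype as the only term, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. CPM values are counts scaled by TMM library sizes. An error given with a log2 fold change is its standard error (SE), the absolute log2 fold change divided by the square root of the quasi-likelihood F. Gene lists with at least 3 tested genes were compared with all other genes by camera (limma 3.58.1) with a correlation of 0.01 between genes, adjusted over 35 lists, and again with an estimated correlation. The lists were also tested with fry, which asks whether a list's genes move, on balance, one way and compares them with no other genes. Members were also adjusted over the list alone. Transcript usage was tested with edgeR's diffSpliceDGE on rounded transcript counts in genes with at least 2 tested transcripts, with a Simes p per gene. Because that test made too many false calls on simulated data, 2 tests with a spread per transcript were added after seeing the data: limma on the log-ratio of a transcript to the rest of its gene, and edgeR with the gene total as offset. Both were picked from several tests tried on simulated data, at a time when their counts on these libraries were also seen.

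The 36 gene lists comprised 29 programs and 7 sets of cell type markers. The programs were the m6A writer complex, m6A readers and erasers, T cell receptor signalling, store-operated calcium entry and NFAT, death receptors and necroptosis, mitochondrial apoptosis, p53 targets, immediate early genes, NF-kappaB targets, Th1, Th2, Th17, regulatory and follicular helper T cells, inhibitory receptors, naive and memory T cells, IL-2, IL-7 and SOCS signalling, chemokine receptors and integrins, DNA replication, mitosis, interferon-stimulated genes, stress responses, glycolysis, oxidative phosphorylation, cholesterol synthesis, splicing regulators, mRNA decay factors, Roquin and Regnase-1 targets and ribosomal proteins. The marker sets were for B cells, CD8 T cells, NK cells, macrophages and monocytes, dendritic cells, granulocytes, and erythroid cells and platelets. Named genes were Wtap, Orai1 and Ripk1; the 8 largest rises and 8 largest falls among called genes with a mean of at least 10 CPM in the higher group, groups that did not overlap and a symbol that is not a clone or predicted model; the 4 smallest p-values in each direction under the same filters among genes not already named by fold; up to 4 members per list by smallest p; and the 5 smallest p-values for transcript usage.

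On simulated counts with the means and library sizes of these samples, 17114 genes tested and 200 genes changed per run, the gene test recovered 14.9% of genes changed by 1.5-fold, 45.3% of those changed by 2-fold and 83.3% of those changed by 4-fold over 3 runs, with 8.3% false calls and 0 calls of the wrong sign. In separate draws of those runs camera called 0 of the 35 fixed lists and found a list of 20 genes changed by 1.5-fold in 3 of 3 runs. Genes were drawn independently of each other, so this does not show how camera does on lists whose genes are correlated. For transcript usage 9075 genes were tested, and 200 of those with a mean of at least 200 counts were changed. In these the most abundant transcript was lowered 3-fold and the next raised 3-fold, so their ratio shifted by more than 3-fold. Of the changed genes diffSpliceDGE recovered 62.5% with 40.2% false calls, the log-ratio test recovered 74.5% with 12.4% false calls and the gene-total offset test recovered 34.0% with 0 false calls.

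Alternatives were DESeq2 size factors, the DESeq2 Wald test (DESeq2 1.42.0), limma on log2(TPM + 1), no low-count filter, at least 1 CPM in 3 libraries, length-scaled TPM counts, unmatched transcripts kept, the replicate number as a block, an offset on gene length per library, thinning to the smallest library and leaving out each library in turn. An offset on GC content, a fit of 2 against 2 libraries (without WT 1, which correlated least with its group, and the male Wtap KO 3) and the 2 usage tests were added after seeing the data. Libraries of 1 group differed by far more than sampling noise, with a chi-square per degree of freedom of 11.5 or more for each pair, so no library was counted as a copy of another. Tests for the closing section used Python 3.11.15 with scipy 1.17.1. The CLIP experiments that the series mentions were not analysed here. The values of 1 gene that the rule for named genes takes were withheld and are left out.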

Results

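The series compared CD4+ T cells of wild-type mice with CD4+ T cells labelled as Wtap knockout, after activation through CD3 and CD28 in Th1 conditions and culture in IL-2. Wtap is a regulatory subunit of the nuclear complex that methylates adenosines in mRNA (m6A). The question was what its loss does to T cells, with receptor signalling and survival in view. RNA abundance was measured by mRNA sequencing in 3 WT and 3 Wtap KO libraries. The WT libraries held 36641082, 32363139 and 38546728 estimated counts and the Wtap KO libraries 37121040, 40754960 and 44039467. The labels do not say that each library came from its own animal, so p-values measure the spread between these samples. Library 3 of the Wtap KO group had the pattern of a male animal, with the Y-linked Kdm5d at 63.3 CPM against 2.43 to 3.53 CPM in the other libraries. Its Xist level was 3.81 CPM, against 1980 to 4448 CPM in the others.

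Total Wtap RNA did not pass the test, but the shares of some of its transcripts changed. Wtap (ENSMUSG00000060475, GRCm38 chromosome 17, 12966796 to 12994169, minus strand) was at 105 ± 9.99 CPM (SD, n = 3) in WT and 117 ± 3.00 CPM in Wtap KO. Its log2 fold change was 0.16 ± 0.10 (SE), with an adjusted p of 0.371 in edgeR's quasi-likelihood test. The transcript Wtap-205 was at 22.7 ± 4.38 TPM in WT and 5.09 ± 0.435 TPM in Wtap KO. Wtap-201 was at 17.6 ± 1.28 and 38.3 ± 2.94 TPM, and Wtap-203 at 0.079 ± 0.136 and 9.68 ± 1.60 TPM. Wtap-204 was at 4.68 ± 1.28 and 4.13 ± 0.031 TPM. In the annotation Wtap-201 and Wtap-203 have 8 exons, whereas Wtap-204 and Wtap-205 end in an extended exon 6, which in Wtap-205 spans 12973552 to 12975474. First exons differ as well. They lie within 12992077 to 12992259 in Wtap-201 and Wtap-204 and within 12992309 to 12992546 in Wtap-203 and Wtap-205. The changes are thus not tied to the last exon alone. Wtap-205 made up 51.3% ± 4.19 of the gene's estimated counts in WT and 10.0% ± 1.10 in Wtap KO. Transcript usage of Wtap differed in edgeR's diffSpliceDGE (adjusted p = 8.44e-08), in the limma log-ratio test (adjusted p = 0.00567) and in the edgeR gene-total offset test (adjusted p = 0.0213). By transcript, diffSpliceDGE called Wtap-203 (adjusted p = 6.26e-08) and Wtap-205 (adjusted p = 6.35e-05). It did not call Wtap-201 (adjusted p = 0.354) or Wtap-204 (unadjusted p = 0.326). The labels do not state which part of Wtap was deleted, so total reads do not check the deletion, and shares also depend on how reads of a partly deleted gene are assigned.

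**Figure D1:**
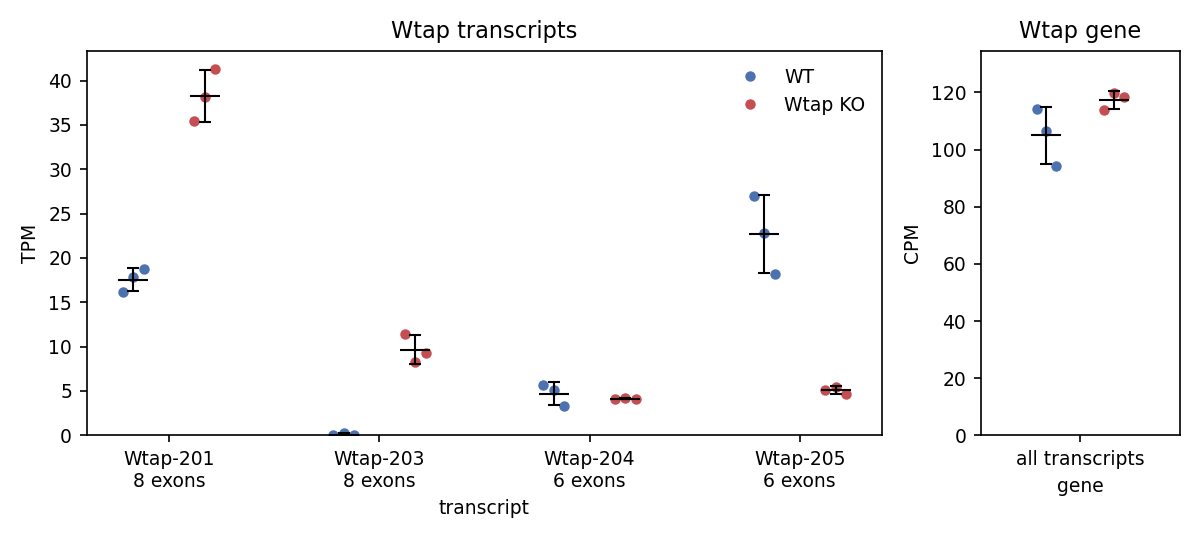
Wtap RNA in the 3 WT libraries (blue) and 3 Wtap KO libraries (red), in TPM for 4 transcripts on the left and CPM for the whole gene on the right, with points for libraries, dashes for means and bars for the SD. Wtap-205 goes from a mean of 22.7 to 5.09 TPM and Wtap-201 from 17.6 to 38.3 TPM, while the gene's mean is 105 CPM in WT and 117 CPM in Wtap KO.

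Of 17610 genes tested, 1626 passed the threshold in edgeR's quasi-likelihood test, 1012 of them higher and 614 lower in Wtap KO. Among these, 482 were higher and 175 were lower by 2-fold or more, and 1381 were protein-coding. In all 1626 genes the WT and Wtap KO libraries did not overlap, which also held for 32.7% of all genes tested, against 10% by chance. The share of calls that were higher was 62.2%, but 73.8% with limma on log2(TPM + 1), 46.3% with an offset on gene length and 41.9% with an offset on GC content that was chosen after seeing the data. The number of genes was 565 without WT 2, 397 without Wtap KO 1, 361 without Wtap KO 2, 704 without the male library Wtap KO 3 and 2576 with the DESeq2 Wald test.

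Among genes with a mean of at least 10 CPM in the higher group, the rises with the largest folds included a cytokine, a chain of antigen presentation and an interferon-induced gene. Il21, a cytokine of helper T cells, went from 0.370 ± 0.356 CPM (SD, n = 3) in WT to 13.4 ± 1.96 CPM in Wtap KO (log2 fold change 5.21 ± 0.47, edgeR adjusted p = 0.00117). Omg rose from 0.831 ± 0.246 to 14.2 ± 2.51 CPM. Ecm1 rose from 37.9 ± 5.58 to 170 ± 42.5 CPM and Plekho1 from 2.84 ± 0.503 to 10.3 ± 0.737 CPM. Cd74, the invariant chain of MHC class II, rose from 5.24 ± 4.15 to 29.5 ± 5.94 CPM. Rtp4, an interferon-induced gene, rose from 25.6 ± 9.86 to 98.9 ± 19.3 CPM. Serpina3g, a protease inhibitor, rose from 13.5 ± 8.39 to 51.8 ± 5.67 CPM and Parm1 had a log2 fold change of 1.92 ± 0.38. Of genes chosen by p and not by fold, Hipk2, a nuclear kinase, rose from 29.9 ± 2.07 to 89.2 ± 6.35 CPM and Dapk1, a death-associated kinase, from 4.98 ± 0.280 to 17.0 ± 1.10 CPM. Nxt1, an mRNA export factor, rose from 21.8 ± 2.05 to 60.8 ± 4.18 CPM and Arl4a from 13.7 ± 0.742 to 34.4 ± 0.992 CPM. Without single libraries Cd74 lost the threshold (without WT 1, WT 3 or any Wtap KO library, edgeR adjusted p up to 0.119), as did Serpina3g (without WT 1 or any Wtap KO library, up to 0.182) and Parm1 (without WT 2, Wtap KO 1 or Wtap KO 2, up to 0.0898).

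Among the falls, Snn went from 26.1 ± 6.70 to 4.09 ± 0.430 CPM (SD, n = 3; log2 fold change -2.67 ± 0.22, edgeR adjusted p = 0.00108). Its exons overlap Litaf and Txndc11 on the opposite strand. Ampd1, an AMP deaminase, had a log2 fold change of -2.31 ± 0.21. Fam102b fell from 108 ± 22.5 to 35.8 ± 3.80 CPM, Plpp6 from 27.2 ± 1.74 to 9.22 ± 1.17 CPM and Eid1 from 22.4 ± 8.08 to 7.59 ± 0.597 CPM. Vegfa, a growth factor of blood vessels, fell from 11.9 ± 4.40 to 4.07 ± 0.365 CPM and Epas1, a hypoxia-inducible factor, from 17.1 ± 3.97 to 6.08 ± 0.960 CPM. The mitochondrially encoded mt-Nd3 fell from 39.0 ± 5.89 to 14.1 ± 5.71 CPM. Chosen by p, Tlr1, a receptor for bacterial lipoproteins, fell from 184 ± 9.84 to 86.0 ± 1.93 CPM and Olfr1033 from 44.6 ± 4.41 to 18.9 ± 1.58 CPM. Slfn1, which has close paralogs, fell from 265 ± 6.83 to 135 ± 8.59 CPM. Rap2b, a small GTPase, fell from 39.2 ± 1.44 to 18.2 ± 0.706 CPM, as did the overlapping opposite-strand Gm37696 (log2 fold change -1.53). Vegfa lost the threshold without Wtap KO 1 or 3 (edgeR adjusted p up to 0.0591) and mt-Nd3 without WT 1, WT 2, Wtap KO 1 or Wtap KO 2 (up to 0.0850).

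**Figure D2:**
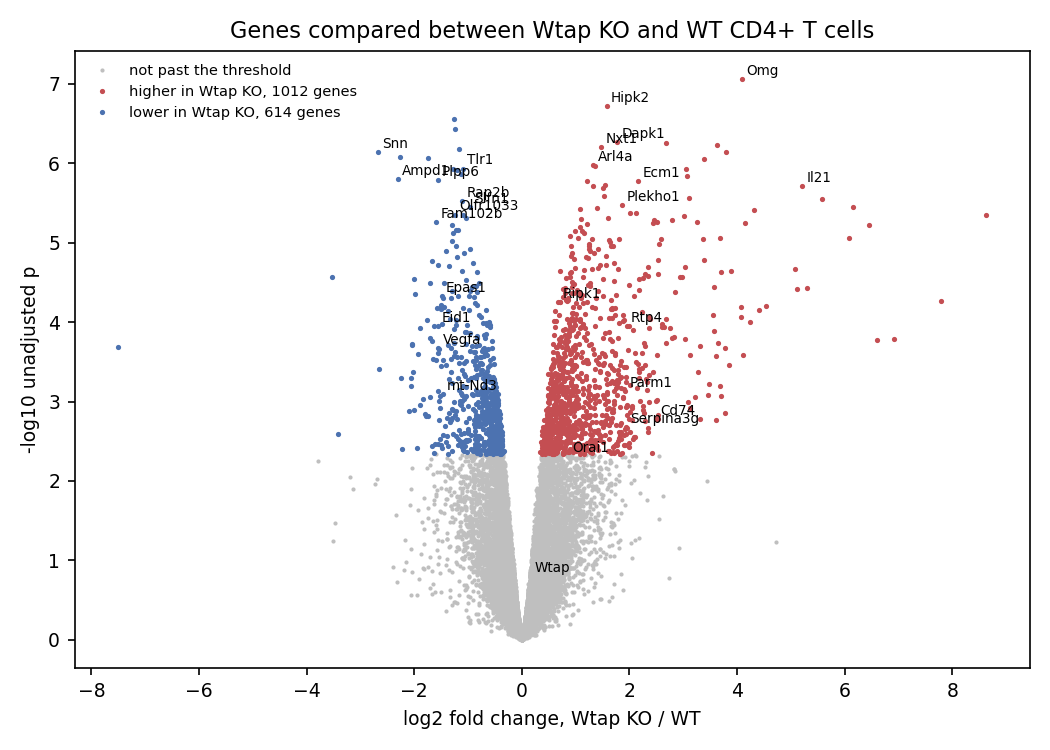
Each point is 1 of 17610 genes, with the log2 fold change of Wtap KO over WT on the x axis and -log10 of the unadjusted edgeR p on the y axis. Genes past the threshold are red where higher (1012) and blue where lower (614), and Wtap lies near the middle at 0.16.

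Part of the genes of death receptor signalling and of the NF-kappaB pathway rose, 7 of 23 and 10 of 20. Ripk1, a kinase that links death receptors to cell death and NF-kappaB, went from 62.2 ± 1.15 CPM (SD, n = 3) in WT to 99.6 ± 5.10 CPM in Wtap KO (log2 fold change 0.68 ± 0.09, edgeR adjusted p = 0.00520). Of 23 genes of death receptors and necroptosis, 7 rose, 0 fell and 16 did not pass, and 10 rose when adjusted over the list alone. Zbp1, a sensor of nucleic acids, rose from 104 ± 11.7 to 166 ± 13.4 CPM and Tnf from 9.89 ± 2.29 to 18.8 ± 1.52 CPM. Birc3, an inhibitor of apoptosis, had a log2 fold change of 1.26. The list was higher by camera (adjusted p = 4.12e-05; adjusted p = 0.252 with an estimated correlation). Of 20 NF-kappaB targets, 10 rose and 0 fell, and 12 rose when adjusted over the list alone (camera adjusted p = 9.83e-09; adjusted p = 0.446 with an estimated correlation). Nfkbie, an inhibitor of the pathway, rose 2.15-fold, Bcl3, a nuclear co-regulator of it, rose 1.97-fold and the adhesion molecule Icam1 rose 1.71-fold, while Birc3 and Tnf stood in both lists. Zbp1, Tnf, Nfkbie, Bcl3 and Icam1 each lost the threshold without 1 or more of WT 2, Wtap KO 1, Wtap KO 2 and Wtap KO 3, with an edgeR adjusted p of up to 0.0951 for Tnf.

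Of 31 interferon-stimulated genes tested, 15 rose, 1 fell and 15 did not pass, and 19 rose and 2 fell when adjusted over the list alone (camera adjusted p = 4.59e-11; adjusted p = 0.446 with an estimated correlation). Usp18, which restrains interferon signalling, rose from 8.12 ± 0.890 to 23.0 ± 1.34 CPM (SD, n = 3). The transcription factor Stat2 rose from 50.0 ± 1.67 to 108 ± 13.9 CPM and Oas2, a sensor of double-stranded RNA, from 0.650 ± 0.323 to 7.86 ± 3.57 CPM. Markers of dendritic cells moved the same way, with a summed level of 25.3 ± 13.4 TPM in WT and 54.3 ± 8.62 TPM in Wtap KO. Of their 10 tested genes, 3 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.00119; adjusted p = 0.446 with an estimated correlation). These were H2-Aa (1.41 ± 0.977 to 6.18 ± 1.23 CPM), Batf3 (1.75 ± 0.886 to 6.49 ± 1.39 CPM) and Cd74. H2-Aa and Batf3 each lost the threshold without 1 or more of WT 2, Wtap KO 1, Wtap KO 2 and Wtap KO 3, with an edgeR adjusted p of up to 0.0872 for Batf3.

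Of 29 p53 targets, 9 rose and 1 fell, and 13 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.00142; adjusted p = 0.446 with an estimated correlation). Zmat3 rose from 131 ± 10.3 to 222 ± 10.3 CPM (SD, n = 3), Phlda3 from 5.71 ± 1.10 to 12.9 ± 0.151 CPM and the death receptor Tnfrsf10b from 13.8 ± 1.22 to 22.0 ± 2.23 CPM. Sesn1 fell from 93.3 ± 7.97 to 51.2 ± 5.90 CPM. Of 24 genes of the integrated stress and unfolded protein responses, 4 rose and 0 fell, and 5 rose when adjusted over the list alone (camera adjusted p = 0.00627; adjusted p = 0.446 with an estimated correlation). The chaperones Pdia4 and Hspa5 rose from 70.9 ± 3.99 to 132 ± 6.26 CPM and from 146 ± 14.4 to 248 ± 9.23 CPM. Of 20 genes of mitochondrial apoptosis, 3 rose and 0 fell, and 5 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.240). Bax, which permeabilises mitochondria, rose from 44.9 ± 7.57 to 67.3 ± 4.27 CPM, and the protective Mcl1 and Bcl2l2 rose 1.44-fold and 1.89-fold. Tnfrsf10b, Bax, Mcl1 and Bcl2l2 each lost the threshold without 1 or more of WT 2, Wtap KO 1, Wtap KO 2 and Wtap KO 3, with an edgeR adjusted p of up to 0.134 for Bax.

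Of 32 genes of T cell receptor signalling, 1 rose, 2 fell and 29 did not pass, and 1 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.240). Cd3g, a chain of the receptor complex, fell from 429 ± 45.4 to 279 ± 18.8 CPM (SD, n = 3) and the co-receptor Cd4 from 542 ± 62.5 to 378 ± 12.8 CPM, while the adaptor Nck1 rose 1.54-fold. Of 27 genes of store-operated calcium entry and NFAT, 2 rose and 1 fell, and 3 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.553). The calcium sensor Stim2 rose 1.37-fold, Nfatc2 rose 1.39-fold and the calcineurin subunit Ppp3cb had a log2 fold change of -0.54. Orai1 (ENSMUSG00000049686, GRCm38 chromosome 5, 123015074 to 123030456), the pore of the store-operated calcium channel, was at 21.3 ± 7.29 CPM in WT and 38.5 ± 4.14 CPM in Wtap KO. Its log2 fold change of 0.86 ± 0.23 did not pass (edgeR adjusted p = 0.0517). Without single libraries its adjusted p ran from 0.0109 to 0.178 in edgeR and passed without WT 1 or WT 3, and it also passed with the DESeq2 Wald test among other settings. Of 26 immediate early genes of activation, 4 rose and 0 fell, and 6 rose when adjusted over the list alone (camera adjusted p = 0.000719; adjusted p = 0.446 with an estimated correlation). The transcription factors Egr3 and Egr2 rose 3.70-fold and 3.08-fold, Egr1 from 1.90 ± 0.387 to 4.44 ± 0.933 CPM and Jun from 8.61 ± 0.650 to 12.9 ± 0.874 CPM. Cd3g, Cd4, Nck1, Stim2, Nfatc2, Ppp3cb, Egr2, Egr1 and Jun each lost the threshold without 1 or more of WT 2, WT 3, Wtap KO 1, Wtap KO 2 and Wtap KO 3, with an edgeR adjusted p of up to 0.177 for Stim2.

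Genes of helper T cell subsets moved in mixed directions. Of 24 Th1 genes, 3 rose and 0 fell, and 3 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.203). The receptor subunit Il12rb1 rose 2.20-fold, the chemokine Ccl5 1.76-fold and Id2 1.62-fold. Of 8 tested Th2 genes, Il1rl1 rose 3.07-fold and the regulator Gata3 fell from 97.0 ± 23.8 to 56.0 ± 2.78 CPM (SD, n = 3), with 3 rises and 1 fall when adjusted over the list alone (camera adjusted p = 0.158). Of 8 tested Th17 genes, 3 rose and 0 fell, and 4 rose when adjusted over the list alone (camera adjusted p = 0.00406; adjusted p = 0.510 with an estimated correlation). These were Il23r (3.21-fold), Tmem176a (3.57 ± 0.172 to 7.14 ± 1.08 CPM) and Tmem176b (1.95-fold), and the camera call was lost without WT 3. Of 14 regulatory T cell genes, Nrp1 and Itgae rose 2.07-fold and 2.01-fold and the inhibitory receptor Ctla4 fell from 186 ± 35.7 to 102 ± 7.49 CPM, with 4 rises and 2 falls when adjusted over the list alone (camera adjusted p = 0.204). Of 12 follicular helper genes, 3 rose and 2 fell, and 4 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.180). The rises were Il21, Cxcr5 (3.27-fold) and Cd200 (34.7 ± 2.84 to 51.9 ± 4.64 CPM), and Tox fell from 24.7 ± 5.83 to 14.9 ± 1.91 CPM. Of 16 inhibitory receptors and exhaustion genes, 0 rose and 2 fell, Ctla4 and Tox, with 3 rises and 4 falls when adjusted over the list alone (camera adjusted p = 0.793). Il12rb1, Ccl5, Id2, Il1rl1, Gata3, Il23r, Tmem176a, Tmem176b, Itgae, Ctla4, Cxcr5, Cd200 and Tox each lost the threshold without 1 or more of WT 2, WT 3, Wtap KO 1, Wtap KO 2 and Wtap KO 3, with an edgeR adjusted p of up to 0.178 for Itgae.

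Of 18 genes of naive and memory T cells, 2 rose and 1 fell, and 3 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.598). The homing receptor Ccr7 rose from 381 ± 60.1 to 717 ± 68.9 CPM (SD, n = 3) and Igfbp4 rose 1.57-fold, while Id3 fell from 25.1 ± 6.42 to 12.6 ± 3.35 CPM. Of 24 chemokine receptors and integrins, 4 rose and 1 fell, and 5 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.508). Selplg, a selectin ligand, rose 1.56-fold. Of 21 genes of IL-2, IL-7 and SOCS signalling, the cytokines Osm (1.63-fold) and Lif (3.38-fold) rose and 0 fell, and 3 rose when adjusted over the list alone (camera adjusted p = 0.101). The IL-2 receptor chain Il2ra was at 495 ± 152 CPM in WT and 878 ± 163 CPM in Wtap KO (edgeR adjusted p = 0.0596). Igfbp4, Id3, Selplg, Osm and Lif each lost the threshold without 1 or more of WT 1, WT 2, WT 3, Wtap KO 1, Wtap KO 2 and Wtap KO 3, with an edgeR adjusted p of up to 0.209 for Lif.

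Part of the genes of oxidative phosphorylation, glycolysis and mitosis fell, 9 of 25, 2 of 22 and 5 of 24. Of 25 tested genes of oxidative phosphorylation, 0 rose and 9 fell, and 14 fell when adjusted over the list alone (camera adjusted p = 2.09e-06; adjusted p = 0.446 with an estimated correlation). Ndufv2 fell from 112 ± 7.97 to 78.8 ± 4.45 CPM (SD, n = 3) and Atp5b from 379 ± 31.4 to 267 ± 21.1 CPM. Of 22 glycolysis genes, 0 rose and 2 fell, and 9 fell when adjusted over the list alone, with a median log2 fold change of -0.64 (camera adjusted p = 7.44e-05; adjusted p = 0.549 with an estimated correlation). In summed TPM the glycolysis list was at 10948, 7172 and 5484 in the WT libraries, with WT 1 highest, and at 5408, 5177 and 3860 in the Wtap KO libraries. The list's median log2 fold change was -0.31 without WT 1 and Wtap KO 3, a setting chosen after seeing the data. Pgam1 fell from 269 ± 91.4 to 147 ± 22.1 CPM and Ldha from 709 ± 132 to 460 ± 72.3 CPM. Of 24 mitosis genes, 0 rose and 5 fell, and 1 rose and 8 fell when adjusted over the list alone (camera adjusted p = 0.000137; adjusted p = 0.590 with an estimated correlation). The median log2 fold change of mitosis genes was -0.30, and -0.14 without WT 1. In summed TPM that list was at 2761 in WT 1 against 2065 and 2131 in WT 2 and 3, and at 1891, 1923 and 2027 in the Wtap KO libraries. The cyclin Ccnb2 fell from 210 ± 16.9 to 145 ± 4.39 CPM and Ube2c from 392 ± 38.1 to 274 ± 12.2 CPM. Of 28 genes of DNA replication, Fen1 (22.8 ± 2.28 to 44.8 ± 1.15 CPM) and Tk1 (28.1 ± 4.55 to 56.8 ± 1.42 CPM) rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.240). Of 21 genes of cholesterol synthesis, 0 rose and Idi1 fell, from 117 ± 17.3 to 65.4 ± 16.4 CPM, also when adjusted over the list alone. That list was lower by camera (adjusted p = 0.0147; adjusted p = 0.626 with an estimated correlation), a call lost without Wtap KO 3. Of 31 ribosomal protein genes, 0 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.489). Ndufv2, Atp5b, Pgam1, Ldha, Ccnb2, Ube2c and Idi1 each lost the threshold without 1 or more of WT 1, WT 2, Wtap KO 1, Wtap KO 2 and Wtap KO 3, with an edgeR adjusted p of up to 0.151 for Pgam1.

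Of the 8 genes of the m6A writer complex, Wtap included, 0 rose and 0 fell, and Cbll1 rose when adjusted over the list alone (camera adjusted p = 0.508). The catalytic subunit Mettl3 was at 21.4 ± 3.92 CPM (SD, n = 3) in WT and 17.6 ± 0.340 CPM in Wtap KO (edgeR adjusted p = 0.278). Of 15 m6A readers, erasers and other m6A enzymes, 3 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.489). All 3 belong to the YTH family that binds m6A: Ythdf2 rose from 64.6 ± 6.09 to 122 ± 6.03 CPM, Ythdf1 from 80.9 ± 4.71 to 118 ± 5.61 CPM and Ythdc1 by a log2 fold change of 0.40. Of 34 mRNA decay factors, Zc3h12d rose from 68.1 ± 9.03 to 151 ± 11.0 CPM and Ddx6 fell from 334 ± 12.7 to 260 ± 6.82 CPM, with 1 rise and 0 falls when adjusted over the list alone (camera adjusted p = 0.523). Of 16 Roquin and Regnase-1 targets, Tnf and Nfkbiz (1.70-fold) rose and Ctla4 fell, with 3 rises and 2 falls when adjusted over the list alone (camera adjusted p = 0.377). Of 29 splicing regulators, 2 rose and 2 fell, and 2 rose and 5 fell when adjusted over the list alone (lower by camera, adjusted p = 0.00627; adjusted p = 0.587 with an estimated correlation). Son rose from 468 ± 15.9 to 710 ± 43.5 CPM and Rbfox2 from 0.325 ± 0.0724 to 1.06 ± 0.340 CPM, while Srsf5 fell from 412 ± 23.6 to 312 ± 10.2 CPM and Hnrnpd from 185 ± 20.1 to 138 ± 8.15 CPM. Ythdf1, Ythdc1, Ddx6, Nfkbiz, Rbfox2, Srsf5 and Hnrnpd each lost the threshold without 1 or more of WT 1, WT 2, WT 3, Wtap KO 1, Wtap KO 2 and Wtap KO 3, with an edgeR adjusted p of up to 0.190 for Hnrnpd.

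Markers of cell types other than CD4+ T cells were compared as lists. Of 11 tested B cell markers, 2 rose and 0 fell, and 3 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.294). Ebf1 rose from 0.143 ± 0.0288 to 0.651 ± 0.185 CPM (SD, n = 3) and Blk from 0.205 ± 0.102 to 0.731 ± 0.242 CPM. In summed TPM the B cell list was at 521 ± 84.2 in WT and 469 ± 113 in Wtap KO, of which Ighm made up 500 and 453 TPM. Of 6 CD8 T cell markers, Cd8b1 rose (10.1 ± 0.610 to 16.6 ± 2.55 CPM) and 0 fell, and 2 rose when adjusted over the list alone (camera adjusted p = 0.108). Of 6 tested NK cell markers, 0 rose and 0 fell, also when adjusted over the list alone, while the list was higher by camera (adjusted p = 0.0320; adjusted p = 0.587 with an estimated correlation). That call was lost without WT 1, WT 3 or Wtap KO 2. Of 10 tested markers of macrophages and monocytes, Itgam rose (3.79 ± 0.899 to 7.43 ± 1.61 CPM) and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.158). Of 4 tested erythroid and platelet markers, 0 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.611). The granulocyte list had 1 tested gene, Cpa3, with an edgeR adjusted p of 0.209. The Blk call was lost without each library in turn (edgeR adjusted p 0.0543 to 0.154). Ebf1, Cd8b1 and Itgam each lost the threshold without 1 or more of WT 2 and Wtap KO 1, 2 and 3, with an edgeR adjusted p of up to 0.134.

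**Figure D3:**
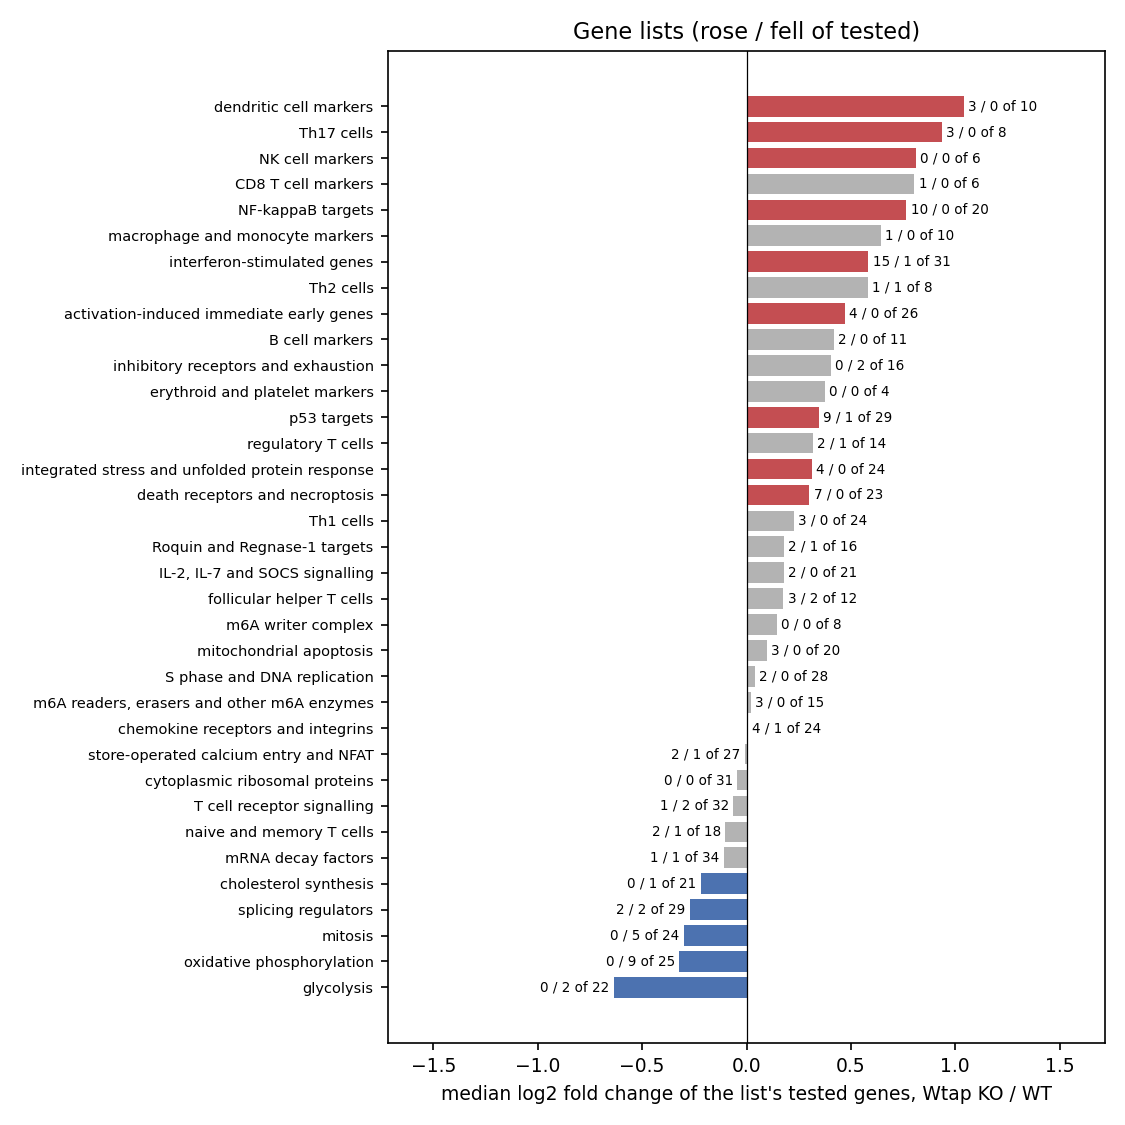
Median log2 fold change of Wtap KO over WT for the tested genes of each of 35 gene lists, with the numbers of genes that rose and fell of those tested beside each bar; red and blue bars mark lists higher or lower by camera with a correlation of 0.01, grey bars the rest. Glycolysis lies lowest at -0.64, and with an estimated correlation 0 of the lists pass the threshold.

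By camera 14 of 35 lists passed the threshold, against 0 with an estimated correlation, where 3 had an unadjusted p under 0.05. In fry, which compares a list with no other genes, 6 lists passed. They were death receptors and necroptosis, p53 targets, NF-kappaB targets, oxidative phosphorylation, dendritic cell markers and mitochondrial apoptosis, the last of which camera did not call. Lists called by camera that did not pass in fry included interferon-stimulated genes (fry adjusted p = 0.0573), glycolysis (fry adjusted p = 0.137) and mitosis (fry adjusted p = 0.150). Of 105 named genes past the threshold in edgeR, 37 were also past it without each library in turn. Without Wtap KO 1 this held for 39 of them, without Wtap KO 2 for 41, without WT 2 or Wtap KO 3 for 54 each, without WT 3 for 93 and without WT 1 for 97.

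**Figure D4:**
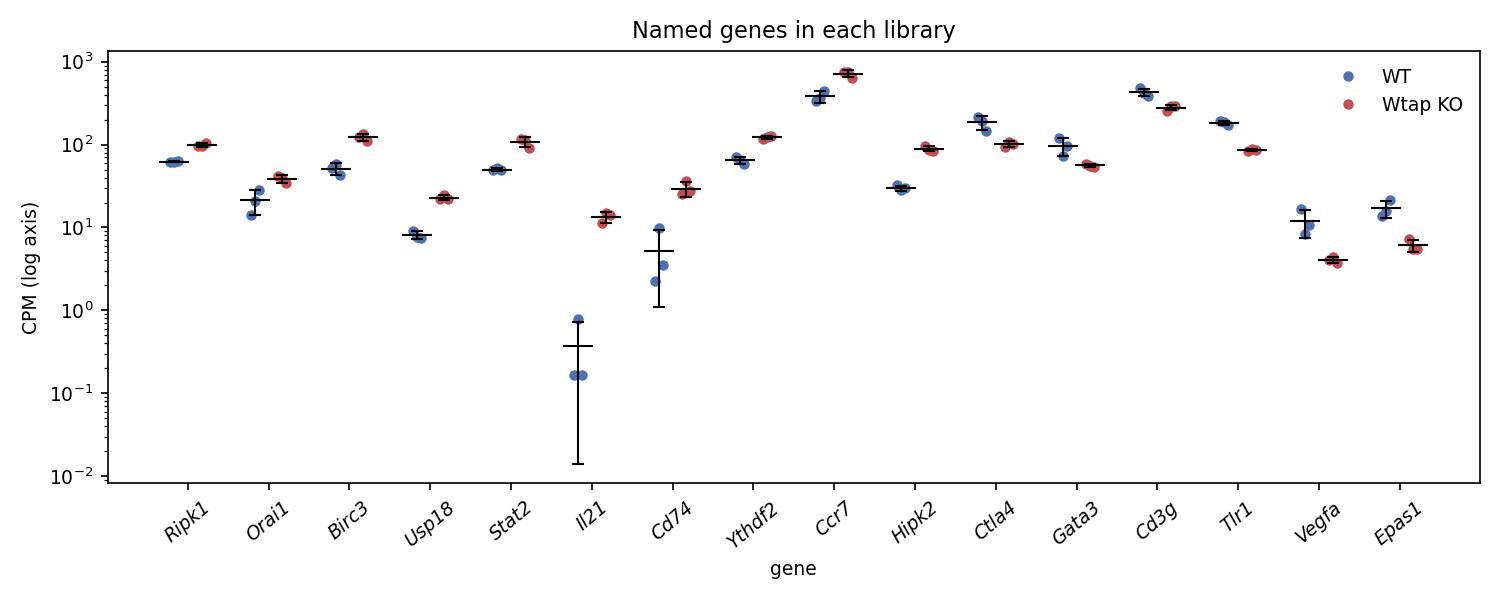
CPM on a log axis for 16 named genes, picked for this plot after their values were seen, in the 3 WT (blue) and 3 Wtap KO (red) libraries, with points for libraries, dashes for means and bars for the SD. Il21 goes from a mean of 0.370 to 13.4 CPM, Ripk1 from 62.2 to 99.6 CPM and Orai1, with an edgeR adjusted p of 0.0517, from 21.3 to 38.5 CPM.

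Transcript shares changed in Ripk1 as well as in Wtap. Ripk1 (ENSMUSG00000021408, GRCm38 chromosome 13, 34002363 to 34037147) has a transcript Ripk1-203 whose last exon spans 34032496 to 34037147. It made up 26.3% ± 1.80 of the gene's estimated counts in WT and 7.77% ± 0.943 in Wtap KO (SD, n = 3). Ripk1-201, whose last exon ends at 34033677, was at 57.8% ± 4.47 and 76.8% ± 2.17. Their first exons differ as well, at 34002874 to 34002953 in Ripk1-203 and 34002363 to 34002706 in Ripk1-201. The change in shares is thus not tied to the last exon. By transcript, diffSpliceDGE called Ripk1-203 (adjusted p = 0.00175) but not Ripk1-201 (unadjusted p = 0.108). Usage of Ripk1 differed in edgeR's diffSpliceDGE (adjusted p = 0.00196), in the limma log-ratio test (adjusted p = 0.0213) and in the edgeR gene-total offset test (adjusted p = 0.0375). Exons of Ripk1 overlap Serpinb6a on the opposite strand and Gm17084 on the same strand. Usage of Orai1 did not pass (diffSpliceDGE in edgeR, unadjusted p = 0.689).

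The smallest p-values for transcript usage belonged to Agpat3, Dido1, Kat14, Ubr2 and Pofut1. Agpat3-211 made up 18.2% ± 7.55 of Agpat3 in WT (SD, n = 3) and was listed at 0% in Wtap KO, where a count of 0 allows up to 0.0301%. Pofut1-204 was listed at 0% in WT, which allows up to 0.126%, and made up 8.65% ± 3.02 of Pofut1 in Wtap KO. Kat14-208 was listed at 6.4e-05% in WT, below the 0.177% that a count of 0 allows for this gene, and made up 14.2% ± 2.52 in Wtap KO. Ubr2-201 was at 1.55% ± 0.535 and 17.0% ± 2.11, and Dido1-205 was listed at 0.00082% and 2.53% ± 0.957. The WT value of Kat14-208 is thus no measured share, and that of Dido1-205 is near 0 as well. None of these 5 genes passed the edgeR gene-total offset test, where their adjusted p ran from 0.0503 to 0.146, while all 5 passed the limma log-ratio test. Of 9404 genes with several tested transcripts, diffSpliceDGE called 153, but 40.2% of its calls on simulated data were false. The tests added after seeing the data called 107 genes (log-ratio) and 40 genes (gene-total offset), and all 3 tests called 18, among them Wtap, Ripk1 and Arl4a. The diffSpliceDGE count was 261 with its gene-level F test, 63 with transcripts holding at least 10% of their gene, 249 without WT 1 and 294 without WT 3.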

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

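No test here was chosen after the result was seen. Some transcripts without a match in GENCODE M21, which the comparison of genes does not use, also differed between the groups. Of 242 unmatched transcripts with enough counts to test, 17 passed the threshold in edgeR when kept as features of their own, 13 higher and 4 lower in Wtap KO. That is no larger a share than the 1626 of 17610 genes in the main test.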

How the results depend on the processing

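An offset on GC content, a fit of 2 against 2 libraries and both added usage tests were chosen after seeing the data. No named gene or list changed direction past the threshold, but the balance of all calls did, with 815 higher and 945 lower under the gene length offset and 959 higher and 1329 lower under the GC content offset. The median log2 fold change of glycolysis genes went from -0.64 to -0.31 with 2 against 2, and that of mitosis genes from -0.30 to -0.13 with 2 against 2 and -0.14 without WT 1. Of 2879 values for 152 named genes under alternatives, 2350 kept their side of the threshold, 402 lost it and 127 gained it, and of 525 values for 35 lists 472 kept it, 30 lost it and 23 gained it. The log2 fold change of Wtap lay between 0.09 and 0.33 and never passed. The 1626 genes (1012 higher, 614 lower) became 2576 with the DESeq2 Wald test (1211 lower), 332 lower with limma on log2(TPM + 1) and 985 lower with 2 against 2. Leaving out each library gave 361 to 2282 genes, 263 to 1361 higher and 98 to 921 lower; the cause was not tested beyond the loss of samples. With the replicate number as a block, 1061 genes passed, 347 of them lower, 588 were higher with the block and the gene length offset together, and 98 genes changed usage. The numbers share no known animal, and same-numbered deviations correlated at -0.103, 0.05 and 0.14, so the block is no pairing. Lists past the threshold went from 14 to 0 with an estimated correlation and to 6 with fry, and ranged from 12 to 19 without single libraries. The 153 usage genes became 261 with the gene-level F test, 63 with the share filter, 40 with the gene-total offset test, 287 with 2 against 2 and 182 to 294 without single libraries. With 3 libraries per group the gene test recovered 14.9% of 1.5-fold changes in simulations with 200 changed genes per run. With the 1626 calls made here the adjusted threshold admits larger p-values, so that share is not the recovery in these libraries. Changes of that size can still be missed.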

Other observations

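The grouping of genes by symbol and biotype, the count without the male library and the test of length bias on the exon pattern were chosen after the result was seen. Of 12923 protein-coding genes tested, 897 (6.9%) rose and 484 (3.7%) fell, a balance that rests on the scaling, since over all genes 46.3% of calls were higher with the gene length offset and 41.9% with the GC content offset. Of 839 long intergenic noncoding RNA genes, 23 (2.7%) rose and 38 (4.5%) fell, a difference between gene types that was not tested. Among genes that share a symbol stem, 27 of 230 Slc transporter genes rose and 4 fell, 8 of 42 genes with the stem Il rose and 1 fell, and 5 of 36 histone genes fell and 0 rose. Of 90 such families 0 passed the threshold in Fisher's exact test, with 6 enriched in rises and 7 in falls at an unadjusted p under 0.05. The lowest adjusted p was 0.337 for rises (Slc and Il) and 0.306 for falls (histone genes among them).

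Among protein-coding genes with at least 3 exons, those with a long internal exon had higher fold changes in Wtap KO than those with only short ones. m6A is dense in long internal exons, so a candidate explanation, set before the data were examined, was that such genes rise when the writer is lost: the median log2 fold change was 0.145 over 2034 genes with an internal exon of 400 nt or longer and -0.034 over 5627 genes with none over 200 nt. Exons, length and GC content of a gene, also for the offsets, were those of its transcript with the highest mean TPM. That transcript can be a short one, as for Son (2449 nt, longest internal exon 189 nt), and other transcripts of a gene can hold longer exons. The 2 classes are thus approximate. Genes with fewer than 3 exons, or with a longest internal exon between the bounds of 200 and 400 nt, were in neither class. The difference was 0.178 (95% bootstrap interval 0.157 to 0.204, across genes, which are not independent replicates), and 11.9% of the former genes rose against 5.42% of the latter. The least difference was 0.147 within a quartile of transcript length and 0.137 within a quartile of GC content. This argues against either bias alone, as measured on the chosen transcript, as the whole source, although m6A itself was not measured in these libraries. The length quartiles were already part of the prediction on long exons, so the later length test adds no separate support. Length also varied within quartiles, the highest of which spanned 3927 to 123179 nt. Fold changes also followed GC content. From its lowest to its highest quartile the medians went from 0.002 to 0.239 with a long internal exon and from -0.135 to 0.071 without. Length and GC content were not held fixed together. On log2 CPM the real split of the 6 libraries gave a difference of 0.158 and the highest other split 0.0984, and 10 splits are too few for a share under 0.05.

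With an offset on gene length 87.5% of the 1626 genes that differed were called in the same direction and after thinning to the smallest library 92.0%, which argues against length or depth as the whole source. The largest difference in summed marker TPM of another cell type was 52.3 TPM (B cell list, lower in Wtap KO, mostly Ighm), under the bound of 1000 TPM set before the data were examined, but dendritic cell markers went from 25.3 to 54.3 TPM and NK cell markers from 11.3 to 21.5 TPM, so a share of other cells in calls such as Cd74 and H2-Aa stays open. Without the male library 704 genes passed, 664 of them among the 1626 and in the same direction. Its sex is not the source of these calls, as the libraries left showed no male pattern. For the other calls sex stays open. The 397 and 361 genes without the other Wtap KO libraries do not decide it, since leaving out a library unlike its group can itself lower the spread. The 100% of calls that kept their direction and most of their fold without the male library decides nothing either, since the groups of every call did not overlap. A p53 response to Cre recombinase or tamoxifen stays open, with a median log2 fold change of 0.347 for p53 targets, because the labels do not say whether WT cells carried Cre and give tamoxifen in a protocol shared by all libraries. The real split gave 1626 genes and 153 usage genes and was the 1 split with counts that large, the highest other giving 0 and 75, but 10 splits are too few for a share under 0.05.

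A hypothesis that rises from a low level reflect transcription running on from an expressed upstream gene was tested. Of 121 genes under 1 CPM in WT that rose 4-fold or more, 26 (21.5%) began inside or within 20 kb downstream of a same-strand gene of at least 10 CPM. The share was 23.1% of 4293 uncalled genes, a difference of -1.6 percentage points, without the predicted excess. On the opposite strand the shares were 10.7% and 23.3%, a difference of -12.6 percentage points (two-sided Fisher's exact test, p = 0.000633). The raised genes thus had fewer expressed neighbours there, so the uncalled genes are no matched baseline and the comparison does not decide on the hypothesis.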
